A study of Mus musculus with 4 samples.

How the data were processed

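RNA was profiled in 4 mouse embryonic fibroblast lines at passage 2 to 3, of which lines 2 and 4 lacked Pf1 and lines 5 and 6 were wild type, per the labels. All 4 lines carried the prefix 7706. Each line was hybridised to 1 Affymetrix array after biotin labelling of total RNA. The series text names the Mouse Genome 430A 2.0 array, whereas the deposited table held 45101 probe sets and matched the probe annotation of the larger Mouse Genome 430 2.0 array, which was the one used here.

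The deposited values were on a log2 scale and came from Affymetrix Expression Console and the RMA method (background correction, quantile normalisation and a log2 summary per probe set), per the submitters' processing notes, with versions not given in the sources used here. The log base is not stated there and was taken from the method. In the deposited log2 table the median of every probe set over the 4 arrays was 0 within 1e-06 (100% of probe sets), so the values had been centred per probe set by a step that the labels do not describe. This centring removes the signal level of each probe set and keeps the differences between arrays. No detection calls, signal over background, scan dates or batches were used here, and the number of arrays limits the precision. The column medians were 0.00258 (knockout line 2), 4.43e-05 (knockout line 4), 0.0045 (wild-type line 5) and -0.00876 (wild-type line 6), and the standard deviations over probe sets were 0.244, 0.202, 0.273 and 0.235.

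Of the probe sets, 64 were controls, 34958 had 1 gene in the platform annotation, 932 had several and 9160 had no gene name there. These classes were counted separately and sum to slightly more than the 45101 probe sets of the table. Symbols were updated through Entrez identifiers against RefSeq genes of assembly GRCm38.p6. This matched 34754 probe sets and changed 0 symbols. Probe sets of several genes were left out of the gene means, and controls were left out of the fit over all probe sets. The gene means had no separate filter on controls, so a control probe set with a gene name could enter them. The plan was to keep, for each gene, the probe set with the highest mean signal. Centred values hold no such level, so the mean of all probe sets of a gene, listed beforehand as the other choice, was used instead. It gave 18194 genes, 9012 of them with more than 1 probe set.

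Knockout minus wild type was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without covariates, because the line numbers differ between the genotypes and nothing else in the labels separates the lines. Passage (2 to 3) and embryonic day (13.5 or 14.5) were not assigned to lines. If either differed between the genotypes, it could not be told apart from the knockout. The fit had 2 residual degrees of freedom per gene and 3.04 prior degrees of freedom. Benjamini-Hochberg adjustment ran over all genes, and a gene was called at an adjusted p under 0.05. Standard errors are those of the moderated fit. The probe sets of Phf12 were tested in a fit over all probe sets. Genes at least 1.5-fold apart whose knockout lines both lay beyond both wild-type lines were counted as well, without a test.

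Gene lists for nucleolar and ribosomal, cell cycle, stress, metabolic, matrix and developmental programs, and for markers of other cell types an embryo torso could hold, were fixed before the data were examined. The 32 lists with at least 5 measured genes were tested with camera from limma at a preset correlation between genes of 0.01 and adjusted over the lists. The same test with an estimated correlation, and fry from limma, were alternatives. Member counts are also given adjusted over the list alone. No pair of lists shared more than 2 measured genes. Lists for fatty acid synthesis, fatty acid oxidation, complement and histone genes were added after the data had been seen.

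Named genes followed a rule fixed in advance: Phf12, the 15 called genes with the largest difference in each direction, up to 4 members per list with the smallest p, and 5 sex-specific transcripts, of which 4 had a named probe set. The 15 genes per direction were chosen among called genes without overlap between the genotypes. Genes of the added lists, neighbours of Phf12 and members named only to complete a count of 5 or fewer called genes were chosen after their values were seen.

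Simulated data had the spread of these 18194 genes, with each gene drawn independently. Effects that many genes of a line share were therefore not covered by the shares of recovered and false calls. The fit was tested on these data. With 200 changed genes, it recovered 3.28% of those changed 1.5-fold, 63.9% of those changed 2-fold and 95.3% of those changed 4-fold, with 4.93% false calls. With 2400 changed genes the shares were 73.3%, 95.0% and 99.4%, with 4.34% false calls. For lists without any change whose genes were correlated at 0.5, camera with the preset correlation called 17.9 of 32 lists on average and camera with an estimated correlation called 0. With uncorrelated genes both called 0.

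The alternatives were every probe set on its own, probe sets of the _x_at and _s_at kind left out, robust eBayes, array weights, arrays centred on their medians, quantile normalisation, sex-specific transcripts left out, other thresholds, other list tests, and each line left out in turn. Quantile normalisation here was run on the centred values. It gave the deviations of all lines the same distribution and did not repeat a normalisation of signal. A filter on low values and an intensity trend need signal levels and were not run. Plots were drawn with matplotlib 3.10.9.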

Results

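Transcript levels were compared between mouse embryonic fibroblasts (MEFs, primary cells grown from dispersed embryo torsos of embryonic day 13.5 or 14.5) with and without Pf1, kept at 6% oxygen. Pf1 is the PHD finger protein encoded by Phf12, a partner of Sin3 and histone deacetylase (Hdac) corepressor complexes, and the study asks about its role in nucleolar integrity. There were 2 knockout lines (2 and 4) and 2 wild-type lines (5 and 6), with 1 array each. Differences are given on the log2 scale, knockout minus wild type, with the standard error (SE) of the fit, for n = 2 lines per genotype. The labels do not say that each line came from a separate embryo, so the p-values measure the spread between these lines.

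The Phf12 transcript was examined first, as a check of the genotype labels. Probe set 1434922_at stood at -0.37 and -0.41 in knockout lines 2 and 4 and at 0.56 and 0.37 in wild-type lines 5 and 6, relative to its median over the arrays. It was lower in the knockout by 1.81-fold (log2 difference -0.86 ± 0.109 SE, limma adjusted p = 0.0213). The other probe set, 1453579_at, showed no detectable difference (0.012, limma adjusted p = 0.965), and the mean of both missed the threshold (-0.42 ± 0.0934, limma adjusted p = 0.0504). Where either probe set lies relative to the deleted part of the gene is not given in the sources used here, and a probe set outside it would not check the labels. With any 1 line left out, the difference of 1434922_at lay between -0.95 and -0.76, with limma adjusted p between 0.0605 and 0.169.

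Across the genome, 2211 of 18194 genes were called (limma adjusted p under 0.05), 947 higher and 1264 lower in the knockout. Of the called genes, 1405 differed by at least 1.5-fold (572 higher, 833 lower) and 446 by at least 2-fold (137 higher, 309 lower). The genes that rose included 62 of 152 ribosome biogenesis genes (2 fell) and 9 of 17 smooth muscle and myofibroblast markers. Those that fell included 16 of 21 cholesterol synthesis genes, 22 of 36 interferon-stimulated genes, 20 of 47 extracellular matrix genes (1 rose) and 10 of 30 genes of glycolysis and the hypoxia response. Camera called these 6 lists with the preset correlation between genes, each with adjusted p = 0.752 with an estimated correlation. Lines of 1 genotype lay closer to each other than to the other genotype. Lines 2 and 4 differed by at least 2-fold at 100 genes and lines 5 and 6 at 168, against 506 to 823 genes between a knockout and a wild-type line. The first principal component held 74.2% of the variance and separated the genotypes, at 30.2 and 22.6 for knockout lines 2 and 4 and -31.3 and -21.5 for wild-type lines 5 and 6. In all, 1752 genes were at least 1.5-fold apart without overlap between the genotypes (747 higher, 1005 lower). Of all genes, 58.2% did not overlap, against 33.3% by chance for genes that vary independently. Only 3 ways of splitting the 4 lines into pairs exist. Effects that many genes of a line share can raise the share in any of them, so the excess over 33.3% is not a test of genotype. With 1 line left out, which leaves 1 residual degree of freedom, limma called 0 genes without knockout line 2, 321 without knockout line 4, 1 without wild-type line 5 and 0 without wild-type line 6, with 3296, 3717, 4486 and 5419 genes at an unadjusted p under 0.05, against 5368 with all 4 lines.

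Fabp7, the fatty acid-binding protein of radial glia, rose most, 9.91-fold (3.31 ± 0.304 SE, limma adjusted p = 0.014). Acta1, skeletal muscle alpha-actin, rose 8.79-fold (3.14 ± 0.233, limma adjusted p = 0.011), and Eno3, the muscle enolase, 5.34-fold (2.42 ± 0.172). Krt8, a keratin of simple epithelia, rose 5.33-fold (2.42 ± 0.21), in all 3 of its probe sets, and the intestinal keratin gene Krt20 rose 3.83-fold (1.94 ± 0.208). Perp and Pmaip1, both targets of p53 with roles in cell death, rose 5.72-fold (2.52 ± 0.304) and 5.12-fold (2.36 ± 0.273). The prolactin family member Prl8a9 (2.72), Bex1 (2.49), the chemokine Ppbp (2.30), the histone H3 gene H3c11 (2.25), the transcription factor Foxd1 (2.20), the procollagen C-proteinase enhancer Pcolce2 (2.13), the receptor Gpr149 (1.98) and the atrial myosin light chain Myl7 (1.96) completed the 15 largest increases. The limma adjusted p of all 15 lay between 0.0103 and 0.0219.

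The largest decrease was that of Agtr2, the type 2 angiotensin receptor, which was 20.6-fold lower in the knockout (-4.36 ± 0.203 SE, limma adjusted p = 0.0103). The matrix proteins Thbs4 (-3.55 ± 0.284), Lum (-3.33 ± 0.591) and Abi3bp (-2.99 ± 0.173) were also among the 15 largest decreases. The interferon-inducible GTPases Iigp1 (-3.16 ± 0.386), Gbp6 (-3.01 ± 0.398) and Gm4951 (-2.82 ± 0.308) fell, as did Ifit3 (-2.80 ± 0.393), Ifi27l2a (-2.66 ± 0.164) and Slfn8 (-2.65 ± 0.4). Selenbp1 (-2.88), the cytokine Il33 (-2.86), the mesodermal homeobox gene Meox1 (-2.82), the protease inhibitor A2m (-2.81) and the opioid precursor Penk (-2.75) made up the rest. The limma adjusted p of these 15 lay between 0.0103 and 0.0339. The 30 genes were taken from called genes whose knockout lines both lay on the same side of both wild-type lines, so their lack of overlap is not a separate result. No called gene overlapped between the genotypes (0 of 2211).

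**Figure D1:**
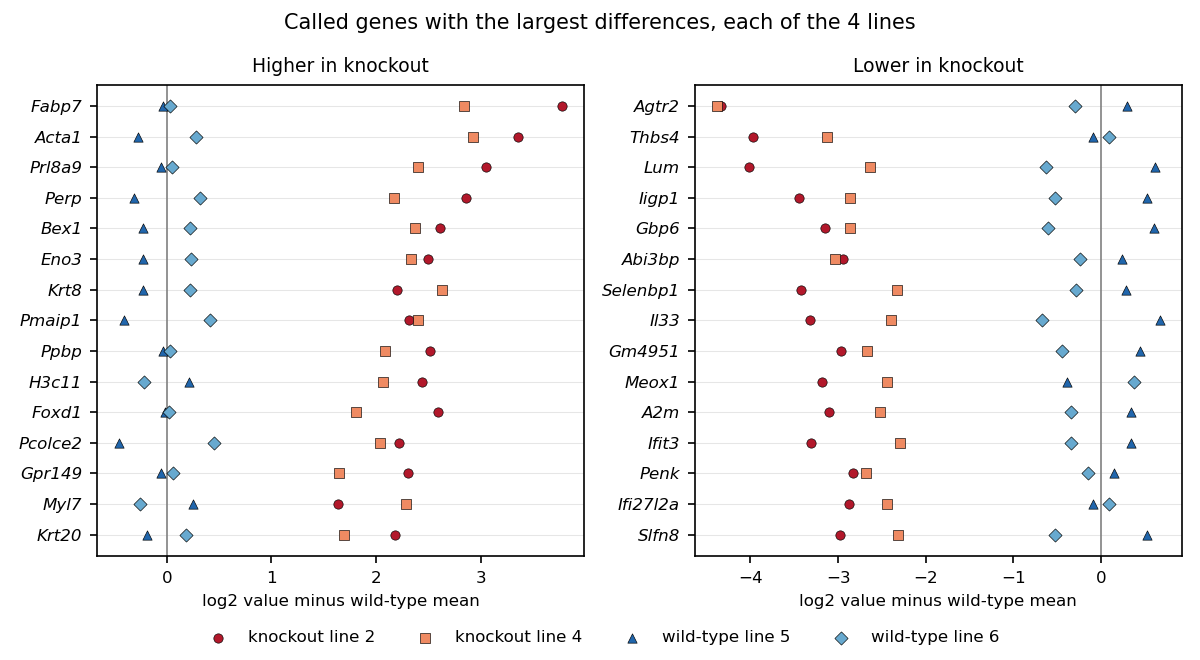
Each point is 1 line's log2 value for the gene on the vertical axis, minus the mean of the wild-type lines, for the 15 called genes with the largest increase (left) and the largest decrease (right). Lack of overlap between the genotypes was a condition for choosing these genes. The differences run from Fabp7 (3.31) to Agtr2 (-4.36).

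Of 32 gene lists, 15 were called by camera with the preset correlation, 9 higher and 6 lower in the knockout. None of these calls held with an estimated correlation (0 of 32 lists, 1 at an unadjusted p under 0.05), and fry called 2 lists, cholesterol synthesis and epithelial markers (adjusted p = 0.026 for both). With an estimated correlation, the adjustment gave all 15 lists the same camera p of 0.752. Their unadjusted camera p ran from 0.0497 (cholesterol synthesis) to 0.585 (respiratory chain). That setting was simulated only on lists without change, so its power to call a real shift is not known. Its correlation is estimated from 2 residual degrees of freedom. For cholesterol synthesis the estimate was 0.168, and the unadjusted camera p moved from 1.98e-16 to 0.0497. An adjusted p of 0.752 is therefore no evidence that a list did not shift. Camera with the preset correlation also called 10 and 12 lists in the other 2 ways of splitting the arrays into pairs, where limma called 0 genes (101 and 276 genes at an unadjusted p under 0.05). Markers of smooth muscle and of epithelia were among the lists that moved with genotype, with median differences of 0.66 and 0.14, beside every group below. Over all genes, 12.2% were called in either direction. Called members were a smaller share in the S phase, mitosis, RNA polymerase I, cytosolic and mitochondrial ribosomal, respiratory chain, chaperone and Nrf2 lists. The same was true of the macrophage, skeletal muscle, adipocyte, cartilage and bone, and erythroid markers. Members named from these lists do not set the lists apart from other genes.

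Genes for ribosome biogenesis, the factors that process ribosomal RNA and assemble ribosomal subunits in the nucleolus, were examined next. Of 152 measured members, 62 rose, 2 fell and 88 did not pass, with 104 higher and 2 lower when adjusted over the list alone. The smallest p-values were those of Nol8 (1.45 ± 0.12 SE, limma adjusted p = 0.0124), Esf1 (1.40 ± 0.129, limma adjusted p = 0.014), the ribosomal maturation factor Rsl24d1 (0.89 ± 0.0889) and the nucleolar SUMO protease Senp3 (0.89 ± 0.103), all higher. Imp3 (-0.44) and Nop53 (-0.40) were the members that fell. The list's median difference was 0.47 (camera adjusted p = 1.21e-23), with adjusted p = 0.752 with an estimated correlation. Relative to the wild-type mean, its median was 0.49 and 0.45 in knockout lines 2 and 4, and -0.11 and 0.11 in wild-type lines 5 and 6. The 18S ribosomal RNA control probe sets averaged 0.64 and 0.07 in knockout lines 2 and 4 and -0.07 and -0.77 in wild-type lines 5 and 6.

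For RNA polymerase I transcription, the step that makes the ribosomal RNA precursor, limma called 0 of 17 measured members, with 7 higher and 0 lower at an unadjusted p under 0.05, 0 when adjusted over the list alone and 1 higher after quantile normalisation. The initiation factor Rrn3 stood at 0.54 ± 0.137 SE (limma adjusted p = 0.069) and the polymerase subunit Polr1e at 0.73 ± 0.199 (limma adjusted p = 0.0792). The list was called as a whole (median 0.25, camera adjusted p = 0.027), with adjusted p = 0.752 with an estimated correlation, and lost its call without knockout line 2 (median 0.22, adjusted p = 0.0756) and without wild-type line 5 (0.13, adjusted p = 0.186), with 0.00114 as the lowest adjusted p over the alternatives. Cytosolic ribosomal proteins, of which 46 of 81 had a named probe set, were not called (median -0.035, camera adjusted p = 0.407). Limma called 0 of them, with 2 higher and 2 lower at an unadjusted p under 0.05 and 0 when adjusted over the list alone. Rpl22 stood at -0.33 ± 0.0807 SE (limma adjusted p = 0.0637).

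Cholesterol synthesis was the list with the largest share of called members. Of 21 measured genes, 16 fell and 5 did not pass, with 18 lower when adjusted over the list alone. Mvd, which makes isopentenyl diphosphate, fell 4.19-fold (-2.07 ± 0.101 SE, limma adjusted p = 0.0103). Hmgcs1, the synthase that forms HMG-CoA, fell 3.06-fold (-1.61 ± 0.0795), the sterol reductase gene Tm7sf2 2.84-fold (-1.51 ± 0.0862) and the sterol-responsive regulator Insig1 3.73-fold (-1.90 ± 0.118). The median difference was -1.19 (camera adjusted p = 2.11e-15, adjusted p = 0.752 with an estimated correlation), at -1.15 and -1.23 in knockout lines 2 and 4 relative to the wild-type mean. The wild-type lines differed little, at -0.029 and 0.029.

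Of 36 measured interferon-stimulated genes, a set with antiviral roles, 22 fell and 14 did not pass, with 33 lower and 1 higher when adjusted over the list alone. Ifi27l2a fell 6.31-fold (-2.66 ± 0.164 SE, limma adjusted p = 0.0103), the GTPase Mx2 3.84-fold (-1.94 ± 0.154), and the transcription factors Stat2 3.05-fold (-1.61 ± 0.145) and Irf7 3.02-fold (-1.59 ± 0.162). The median difference was -1.30 (camera adjusted p = 2.11e-15), with adjusted p = 0.752 with an estimated correlation. Relative to the wild-type mean, the list's median was -1.64 and -0.92 in knockout lines 2 and 4, and 0.21 and -0.21 in wild-type lines 5 and 6. Macrophage markers, a possible other source of these transcripts, had medians of 0.053, 0.76, 0.76 and -0.76 in lines 2, 4, 5 and 6.

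Of 47 extracellular matrix genes of fibroblasts, 20 fell, 1 rose and 26 did not pass, with 25 lower and 2 higher when adjusted over the list alone. The decreases included Loxl3, a lysyl oxidase that cross-links collagen (-1.41 ± 0.0801 SE, limma adjusted p = 0.0103), the proteoglycan Aspn (-1.78 ± 0.144), the fibrillin Fbn2 (-1.17 ± 0.105) and the collagen VI chain Col6a2 (-1.42 ± 0.131), while fibronectin, Fn1, rose (0.50). The list's median was -0.42 (camera adjusted p = 1.28e-07, adjusted p = 0.752 with an estimated correlation). Of 17 smooth muscle and myofibroblast markers, 9 rose and 8 did not pass, with 16 higher when adjusted over the list alone. Smooth muscle myosin Myh11 rose 1.93-fold (0.95 ± 0.0888, limma adjusted p = 0.0144), the adhesion molecule Mcam 2.72-fold (1.44 ± 0.187), the regulatory light chain Myl9 1.62-fold (0.69 ± 0.0964) and desmin, Des, 1.53-fold (0.62 ± 0.0896). Their median was 0.66 (camera adjusted p = 1.79e-08, adjusted p = 0.752 with an estimated correlation), at 0.72 and 0.60 in knockout lines 2 and 4.

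Of 30 measured genes of glycolysis and the hypoxia response, 10 fell and 20 did not pass, with 20 lower when adjusted over the list alone. The pyruvate dehydrogenase kinase Pdk1 (-0.89 ± 0.103 SE, limma adjusted p = 0.0167), the oxygen-sensing prolyl hydroxylase Egln1 (-0.88 ± 0.105), the oxidase Ero1a (-1.65 ± 0.22) and the collagen prolyl hydroxylase P4ha2 (-0.88 ± 0.122) fell. All 30 differences were negative, with a median of -0.53 (camera adjusted p = 7.28e-09, adjusted p = 0.752 with an estimated correlation). Among 34 target genes of Atf4, the transcription factor of the amino acid stress response, 7 fell and 27 did not pass, with 10 lower and 1 higher when adjusted over the list alone. Vldlr (-1.31 ± 0.131), the pseudokinase Trib3 (-1.51 ± 0.19), Cebpb (-1.06 ± 0.188) and Atf5 (-0.56 ± 0.109) fell. This list was called lower (median -0.29, camera adjusted p = 8.39e-05, adjusted p = 0.752 with an estimated correlation), and its median was -0.18 without wild-type line 6. Chaperones of the endoplasmic reticulum were not called (camera adjusted p = 0.494), with Dnajb11 higher (0.75 ± 0.144) and Xbp1 (-0.56 ± 0.112) and Herpud1 (-0.57 ± 0.115) lower among 26 genes. Of 22 Nrf2 targets, the antioxidant genes Txnrd1 (0.62 ± 0.109) and Gclm (0.83 ± 0.179) rose and 20 did not pass (camera adjusted p = 0.375), with 0 when adjusted over the list alone (limma, 7 higher and 3 lower at an unadjusted p under 0.05).

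Of 64 genes of S phase and DNA replication, 6 rose and 58 did not pass, with 10 higher when adjusted over the list alone, 10 higher with array weights and 11 after quantile normalisation. The flap endonuclease Fen1 (1.06 ± 0.129 SE, limma adjusted p = 0.018), the origin recognition subunit Orc1 (0.87 ± 0.158), the helicase Hells (0.80 ± 0.153) and Rpa1 (0.79 ± 0.151) rose. The median was 0.30 (camera adjusted p = 1.78e-06, adjusted p = 0.752 with an estimated correlation), but 0.099 without wild-type line 5 and 0.50 without wild-type line 6. Of 62 mitosis genes, 5 rose and 1 fell, the same counts as when adjusted over the list alone. The condensin subunit Smc2 (0.83 ± 0.117), the kinesins Cenpe (0.87 ± 0.132) and Kif20b (0.47 ± 0.0921), Anln (0.64) and the checkpoint gene Mad2l1 (0.49) rose and the phosphatase Cdc25b fell (-0.72 ± 0.12). The mitosis list was called higher (median 0.18, camera adjusted p = 0.000175, adjusted p = 0.752 with an estimated correlation), but not without wild-type line 5 (median 0.075, adjusted p = 0.147), and its median was 0.30 without wild-type line 6 (adjusted p = 1.44e-08, the lowest over the alternatives).

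Among 10 cell cycle inhibitors, Cdkn2d (-0.83 ± 0.11 SE, limma adjusted p = 0.0197), Cdkn2b (-0.65 ± 0.0868) and Cdkn1b (-0.50 ± 0.0992) fell and Cdkn1a, the p53 target p21, rose (0.41 ± 0.0881, limma adjusted p = 0.0478, not called with array weights), with 4 lower and 1 higher when adjusted over the list alone. The list was not called (camera adjusted p = 0.15). Target genes of p53 went both ways: of 36, 8 rose and 5 fell, and 11 were higher and 6 lower when adjusted over the list alone. Beside Perp and Pmaip1, the stress-response genes Sesn1 (-0.90 ± 0.0821) and Gadd45a (-1.11 ± 0.18) fell, as did Bbc3 (-0.56), Cd82 (-0.53) and Rprm (-0.50). The p53 list was not called (median 0.14, camera adjusted p = 0.0746), but was called without knockout line 4 (median 0.26, adjusted p = 0.0124) and without wild-type line 6 (0.16, adjusted p = 0.0332), while its median was 0.038 without knockout line 2 (adjusted p = 0.449), with adjusted p up to 0.752 over the alternatives. Of 57 senescence-associated secretory factors, 8 fell and 2 rose, with 18 lower and 5 higher when adjusted over the list alone, and 5 lower with robust eBayes and 13 after quantile normalisation. The growth factor-binding proteins Igfbp6 (-1.17 ± 0.0949) and Igfbp4 (-0.87 ± 0.108) and the cytokine receptor subunit Il6st (-1.43 ± 0.146) fell, and the urokinase receptor Plaur (1.37 ± 0.151) and the growth factor Ereg (0.89) rose. The secretory list was called lower (median -0.33, camera adjusted p = 0.0101, adjusted p = 0.752 with an estimated correlation), but not without wild-type line 5 (median -0.20, adjusted p = 0.135), with 0.000242 as the lowest adjusted p over the alternatives.

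Of 77 mitochondrial ribosomal protein genes, 5 rose and 3 fell (4 higher and 3 lower when adjusted over the list alone, 9 and 3 after quantile normalisation), with Mrpl3 (0.90 ± 0.112 SE, limma adjusted p = 0.0184), Mrpl22 (0.62 ± 0.0944), Mrpl20 (0.86), Mrps18c (0.46) and Mrps12 (0.37) higher and Mrpl24 (-0.57 ± 0.087), Mrpl23 (-0.53 ± 0.0824) and Mrps16 (-0.49) lower. Of 72 respiratory chain genes, 3 rose, the complex I subunits Ndufs1 (0.52 ± 0.0946) and Ndufs7 (0.55 ± 0.1) and cytochrome c, Cycs (0.65 ± 0.12), and Ndufv3 fell (-0.51 ± 0.11, not called with array weights). Limma called 0 of the 72 when adjusted over the list alone, with 18 higher and 2 lower at an unadjusted p under 0.05. Both lists were called higher (medians 0.11 and 0.095, camera adjusted p = 0.0109 and 0.0104), each with adjusted p = 0.752 with an estimated correlation. Neither was called without wild-type line 5, where the medians were 0.055 (adjusted p = 0.439) and 0.062 (adjusted p = 0.238), and the mitochondrial ribosomal median was 0.22 without wild-type line 6. Their lowest adjusted p over the alternatives were 2.89e-05 and 0.000126.

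Among developmental regulators, 5 of 33 Hox genes rose and 3 fell, the same counts as when adjusted over the list alone. Hoxa5 (0.69 ± 0.084 SE, limma adjusted p = 0.018), Hoxb6 (0.79 ± 0.103), Hoxb9 (1.16 ± 0.178), Hoxb4 (0.46) and Hoxa7 (0.45) rose and Hoxa11 (-0.68 ± 0.0937), Hoxd13 (-0.77) and Hoxd8 (-0.41) fell. The list was called higher (median 0.21, camera adjusted p = 0.0375, adjusted p = 0.752 with an estimated correlation), but not without knockout line 2 (0.14, adjusted p = 0.076), wild-type line 5 (0.18, adjusted p = 0.0986) or wild-type line 6 (0.14, adjusted p = 0.0679), with 0.0201 as the lowest adjusted p over the alternatives. Of 30 imprinted genes 3 rose and 2 fell (6 higher and 3 lower when adjusted over the list alone), with Zdbf2 (1.05 ± 0.0863), Ndn (0.61 ± 0.082) and Magel2 (0.98 ± 0.203) higher and Mest (-0.86 ± 0.122) and Igf2 (-0.52) lower. Of 23 Notch and Wnt target genes, Notch3 (-1.02 ± 0.0848), Dkk3 (-1.43 ± 0.137) and Dkk2 (-1.09 ± 0.125) fell, also when adjusted over the list alone. Among 27 subunits and partners of the Sin3 and Hdac complexes, Arid4a (0.60 ± 0.088), Arid4b (0.43 ± 0.0815) and Brms1 (0.47 ± 0.0954) rose and the corepressor Tle2 fell (-0.61 ± 0.111), with 4 higher and 3 lower when adjusted over the list alone. Of 29 immediate-early genes 4 rose and 3 fell (5 and 3 when adjusted over the list alone), with Phlda1 (1.34 ± 0.122), Srf (0.76 ± 0.113), Dusp1 (1.06) and Ier5 (0.40) higher and Klf4 (-0.75 ± 0.101), Klf2 (-0.62 ± 0.0845) and Egr1 (-0.61) lower. The imprinted, Notch and Wnt, Sin3 and Hdac, and immediate-early lists were not called (camera adjusted p = 0.628, 0.332, 0.332 and 0.463).

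**Figure D2:**
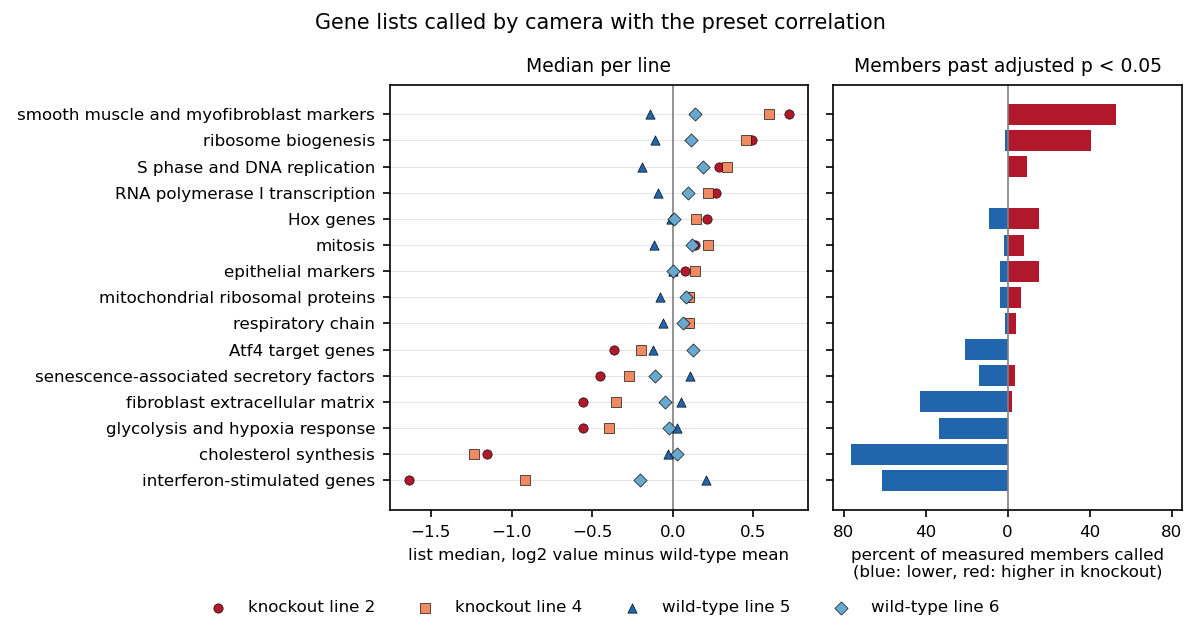
On the left, each point is the median over a gene list of 1 line's log2 values minus the wild-type mean, which makes the wild-type lines mirror images, for the 15 lists that camera called with the preset correlation. On the right, bars give the percent of measured members called lower or higher in the knockout, and the cholesterol synthesis list (16 of 21 lower) and the interferon-stimulated list (22 of 36 lower) have the longest bars.

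Markers of other cell types were examined because a dispersed torso holds more than fibroblasts. Of 26 epithelial markers, Krt8 (2.42 ± 0.21 SE), the desmosomal protein Dsp (1.72 ± 0.235) and the claudins Cldn4 (1.66 ± 0.292) and Cldn3 (0.63) rose, and Krt19 fell (-0.39 ± 0.0813), with 5 higher and 1 lower when adjusted over the list alone. The epithelial list was called higher (median 0.14, camera adjusted p = 0.0375, adjusted p = 0.752 with an estimated correlation), and its median was 0.077 without knockout line 4. Of 26 macrophage markers, Pf4 rose (1.12 ± 0.204, limma adjusted p = 0.0337) and 25 did not pass, with 0 when adjusted over the list alone (limma, 1 higher at an unadjusted p under 0.05). Lyz2, an abundant macrophage transcript, stood at 1.31 ± 0.587 (limma adjusted p = 0.223). The macrophage list was not called (median 0.39, camera adjusted p = 0.0706), but was called higher without knockout line 2 (0.76, adjusted p = 0.000562), without wild-type line 5 (1.06, adjusted p = 2.9e-08) and after quantile normalisation (0.42, adjusted p = 0.034). Its median was 0.053 without knockout line 4 (adjusted p = 0.622) and turned to -0.26 without wild-type line 6 (adjusted p = 0.138), with adjusted p up to 0.752 over the alternatives. Mesothelial markers, with Msln higher (0.59 ± 0.104) and Krt19 lower among 11 genes, were not called (median 0.31, camera adjusted p = 0.264), but were called higher without knockout line 2 (0.68, adjusted p = 5.31e-05), while the median was 0.036 without knockout line 4 (adjusted p = 0.79, the highest over the alternatives).

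Neural and glial markers went both ways, with Fabp7 and Nefm (1.10 ± 0.18 SE) higher and the neuronal growth proteins Stmn2 (-2.21 ± 0.15) and Gap43 (-1.77 ± 0.122) lower, as were Cnp (-0.50) and Isl1 (-0.47), of 23 genes (camera adjusted p = 0.546, 4 higher and 6 lower when adjusted over the list alone). Of 20 endothelial markers Emcn rose (1.85 ± 0.112) and Tek (-0.72 ± 0.147), Ecscr (-0.68 ± 0.107) and Egfl7 (-0.42 ± 0.0873) fell (camera adjusted p = 0.264). Of 29 skeletal muscle markers Acta1 alone passed (camera adjusted p = 0.407). The adipocyte marker Fabp4 fell (-1.39 ± 0.0975) while 13 others did not pass (camera adjusted p = 0.542). Of 25 cartilage and bone markers Col2a1 rose (1.74 ± 0.332) and Sox9 fell (-0.51 ± 0.085) (camera adjusted p = 0.779), and of 14 erythroid markers Hba-a2 fell (-0.47 ± 0.0827) (camera adjusted p = 0.264). Adjusted over the list alone, 2 endothelial markers were higher and 3 lower, 1 skeletal muscle marker was higher, 1 adipocyte and 1 erythroid marker were lower, and 1 cartilage, bone and 1 mesothelial marker went each way. Median, mean and test differed in sign for the adipocyte (median -0.0079, mean 0.0071, camera lower), imprinted (-0.00017, 0.036, higher) and cartilage and bone lists (0.0039, 0.064, lower).

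Sex-specific transcripts set wild-type line 6 apart from the other 3 lines. Xist, the RNA of the inactive X chromosome, stood at 8.08 in line 6 (probe set 1427262_at, relative to its median) and between -0.028 and 0.0076 in lines 2, 4 and 5. The Y-linked transcripts Eif2s3y, Uty and Kdm5d stood at -5.98, -4.86 and -4.64 in line 6 in their probe sets of widest range. None of these genes passed between the genotypes (limma adjusted p from 0.326 to 0.46).

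**Figure D3:**
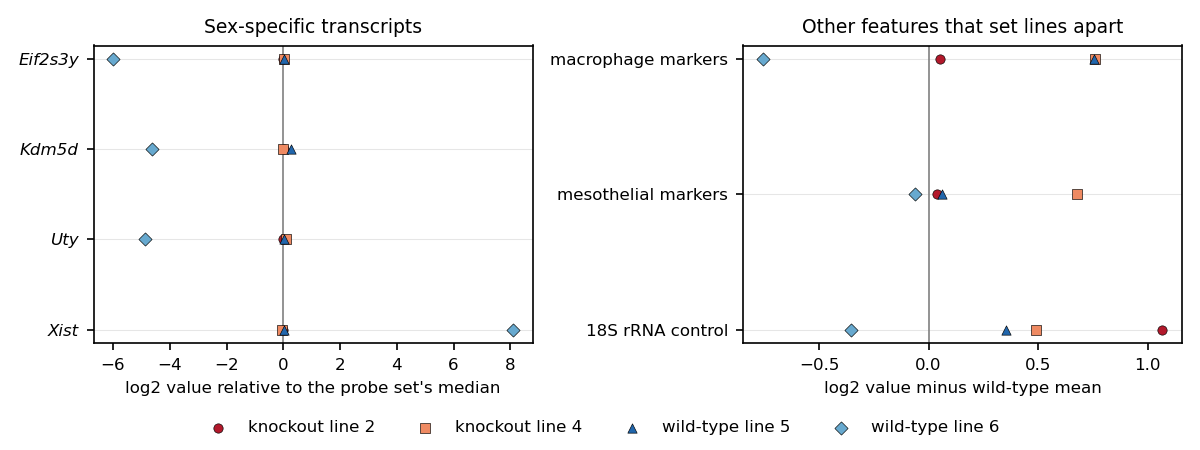
Each point is 1 line. On the left, log2 values of the sex-specific transcripts are given relative to the median of the probe set of widest range, and wild-type line 6 lies at 8.08 for Xist and at -5.98 for Eif2s3y, while the other lines lie near 0. On the right, log2 values minus the wild-type mean are given for the macrophage and mesothelial lists (medians) and the 18S control (mean of 3 probe sets), where lines of 1 genotype lie apart.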

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

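The tests in this part were all chosen after the values had been seen.

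The 3 control probe sets for 18S ribosomal RNA, which no comparison of the report tests, averaged 0.78 higher in the knockout (log2, mean 0.36 against -0.42 in the wild type), with line values of 0.64, 0.07, -0.07 and -0.77 for lines 2, 4, 5 and 6. A value outside the main measurement that stood above the wild-type lines drew attention to it. The Gapdh and Actb probe sets for the 3′ and 5′ ends, which read RNA integrity, gave a 3′ minus 5′ value that differed by 0.046 (Gapdh) and -0.031 (Actb), knockout minus wild type.

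Because ribosome biogenesis genes were higher in the same lines (median 0.47), the amount of ribosomal RNA carried into the labelling was weighed as a technical explanation. Knockout line 4 and wild-type line 5, whose 18S values were close, still differed by 0.55 in the list's median, and knockout lines 2 and 4, whose 18S values were apart, differed by 0.022. A larger share of cycling cells would raise S phase genes too, and the ribosome list's median exceeded that of the S phase list by 0.18 (0.049 to 0.26 over the 4 knockout and wild-type pairs of lines). The same quantity was -0.15 between wild-type lines 6 and 5 and 0.076 between knockout lines 2 and 4, and in both pairs with line 5 (0.12 and 0.049) the excess was smaller in size than the wild-type value. The 18S values argue against ribosomal RNA input as the whole cause, while a larger share of cycling cells and a response to the loss of Pf1 cannot be told apart with these lines, and other differences between the lines were not tested.

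Of the 9160 probe sets without a gene name here, which enter no gene count, 283 passed limma's adjusted test in the fit over all probe sets, 139 higher and 144 lower in the knockout. That fit called 3748 of 45037 probe sets, these among them. Probe sets without a gene name thus passed less often than probe sets in general.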

How the results depend on the processing

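All alternatives in this part were planned, and none was chosen after the result was seen. A filter on low values and an intensity trend in eBayes were not run, because centred values hold no signal level, and for the same reason signal over background could not limit the calls. The mean over the probe sets of a gene, planned as an alternative, was the main setting. No paired analysis was possible because the line numbers differ between the genotypes.

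The count of 2211 called genes (947 higher, 1264 lower) lay between 2133 and 2663 without probe sets of the _x_at and _s_at kind, with robust eBayes, array weights, median-centred arrays, quantile normalisation and sex-specific transcripts left out, and 41.6% to 43.8% of calls were higher. It was 3748 (1767 higher, 1981 lower) with every probe set on its own, where more features are counted, 3890 at an adjusted p under 0.1, and 1405 with a fold of at least 1.5 required. In the fit over every probe set, no probe set passed for the named called genes Atf5, Cdkn1a, Tek, Krt19, Magel2, Ndufv3 and Brms1. Of 1126 called genes with more than 1 probe set, 1030 had the same sign in all of them. The named genes Dsp, Kif20b, Egfl7, Arid4b and Ndn were among those with a probe set of the other sign. The 1752 genes at least 1.5-fold apart without overlap became 4351 with every probe set and 506 at 2-fold, and 1678 to 2209 with a line left out. Leaving out a line leaves 1 residual degree of freedom and a lone line that is assumed to vary like the others. The count of called genes then ran from 0 to 321 (0 to 87 higher, 0 to 234 lower), and 290 of the 321 genes called without knockout line 4 were among the 2211. The difference of Phf12 probe set 1434922_at ran from -0.95 to -0.76 and no longer passed. The other Phf12 probe set, never called, lay at most at 0.075 without each of the other lines and turned to -0.051 without wild-type line 6. The counts without a line rest on fewer arrays and degrees of freedom, and for the probe set the cause was not tested. Of 123 named called genes, 1 to 3 lost their call with the _x_at and _s_at filter, robust eBayes, array weights or quantile normalisation, 72 without knockout line 4 and all 123 without each of the other lines. The 15 called lists became 0 with an estimated correlation and 2 with fry, which test other hypotheses or allow for correlated genes, and numbered 10 to 16 in the other settings.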

Other observations

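The tests of sequence flanking Phf12 and of embryo sex were set before the data were examined. The count over splits, the share of calls on other chromosomes, the tests of macrophage content, wild-type line 5, fatty acid synthesis and histones, and the added gene lists were chosen after the values had been seen.

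Of 20 measured genes of fatty acid synthesis, 12 fell (median -0.44), among them the stearoyl-CoA desaturases Scd1 (-1.94 ± 0.103 SE, limma adjusted p = 0.0103) and Scd2 (-1.51 ± 0.0953), the acetyl-CoA synthetase Acss2 (-1.86 ± 0.108) and the acyl-CoA ligase Acsl3 (-1.05 ± 0.116). Without Scd1, Scd2 and Acss2, which had prompted the list, 52.9% of the other 17 measured members were called lower. Of 15 genes of fatty acid oxidation 4 fell and 2 rose (median -0.15), with Hadh at -0.72 ± 0.0796 and Cpt1a at 0.68 ± 0.101.

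Of 12 complement genes 3 fell (median -0.18): C1s1 (-2.58 ± 0.536 SE, limma adjusted p = 0.0438), C1ra (-2.51 ± 0.361) and C2 (-0.65 ± 0.0993). Of 13 measured histone genes 6 rose (46.2%, median 0.38), namely H3c11, H3c7 (1.64 ± 0.17), H3c4 (1.06 ± 0.113), H2bc22 (0.90 ± 0.0903), H2ac19 (0.88 ± 0.0898) and H1f2 (0.50 ± 0.0809), while 7 did not pass. H1 variants were counted in, among them H1f10 (-0.34), H1f6 (-0.054), H1f7 (0.042) and H1f8 (0.14), which did not pass. H3c11, one of the 15 largest increases, was kept in the count as well. The share of 46.2% depends on these choices and left open whether histone transcripts moved as a class.

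The lower interferon-stimulated genes were weighed against a smaller number of macrophages and against wild-type line 5 alone. Macrophage markers had a median 1.39 higher in knockout line 4 than in wild-type line 6, while the interferon list's median was -0.83 for that pair, but in knockout line 2 against wild-type line 5 they were at -0.63, beside the largest interferon difference of the 4 pairs (-1.80). Without wild-type line 5 the list's median was -1.17, against -1.30 with it. Neither macrophages nor line 5 explain the pattern as a whole, but macrophages may account for part of its size, and an exposure of the cultures that differed between lines was not tested. Such an exposure and a dependence of these genes on Pf1 were not separated by any test here.

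For the called genes as a whole, only 3 splits of the arrays into pairs exist, too few for a share under 0.05: limma called 2211 genes in the real split, which 1 of the 3 reached, and 0 in the highest other. Whether strain sequence carried along beside the deleted gene accounts for some calls was left open. Of the 40 nearest measured neighbours of Phf12, 9 were called (22.5%, against 12.2% of all genes). The one-sided Fisher's exact p was 0.0473, and 0.0945 after Benjamini-Hochberg adjustment over both tests, which misses 0.05. For neighbours at least 1.5-fold apart without overlap, 4 of 40, the same exact test gave p = 0.546. The called neighbours include Tmem199, Trp53i13 and Aldoc (-1.70). On other chromosomes 12.1% of genes were called, against 12.3% on the chromosome of Phf12. The 2027 called genes on other chromosomes lie outside the direct reach of flanking sequence by their position alone. The similar shares therefore do not weigh that explanation for the neighbours. Strain sequence elsewhere in the genome was not tested. Embryo sex did not separate the genotypes, since wild-type line 5 lay 0.015 from the nearest knockout line on the Xist probe set of widest range.

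Between wild-type lines 6 and 5, which differ in sex-specific transcripts, 617 other X-linked genes had a median difference of 0.009, against 0.0075 over 17517 autosomal genes, and 7 of the X-linked genes were at least 2-fold apart.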
